A study of Mus musculus with 18 samples.

How the data were processed

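Gene expression was measured on 18 two-colour Agilent whole mouse genome arrays, each from a sample of sorted thyroid cells labelled with Cy5 and a common reference RNA labelled with Cy3, without a dye swap. Per the labels, RNA was extracted from sorted cells, amplified and labelled, and the design describes biological replicates. The deposited scanner files hold, per spot, the raw intensity of each channel, the local background and signals processed by the scanner software, as intensity per the file headers. They also hold a log10 ratio, which per the file headers is the log10 of processed red over processed green; the values met this within 0.001 on 84.68% of the spots that are not controls. The processed signals had been corrected by the authors with Agilent Feature Extraction, with spatial detrending and a dye normalization; per the labels its version was 8.5.1.1 and per the file headers 9.5.1.1. The values deposited with the series are log2 ratios by the authors for 33040 probes, of which 22551 had a value on all arrays. Their normalization is not stated. Among the columns, 10 matched their own scanner file best and 8 (CSP 2 to CSP 5 and TSP 2 to TSP 5) matched another file of the same group, so arrays are numbered here by the scanner files. The scanner files TSP 1 and TSP 2 were the best match of the columns TSP 1 and TSP 4. The values of the authors served only as an alternative.

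The arrays hold 45018 spots, of which 43379 are not controls, for 41174 probes and 27962 gene names. Raw mean signals were background corrected with the normexp method of limma 3.58.1 (offset 50) and normalized within arrays by loess, with control spots at weight 0. Spots that the scanner software marked as not uniform or as outliers were left out, spots of a probe were averaged, and each gene name was represented by its brightest probe among those well above background in Cy5 on at least 3 of the 18 arrays. This left 20455 genes, of which 19987 had a value on all arrays. Probe names and coordinates (mouse build mm7) are those of the file headers; 22951 probes matched a RefSeq transcript by accession, which served for gene symbols only, and no genome was used. Between 38.8% and 72% of the spots of an array were well above background in Cy5, lowest on slides 1 and 5 (38.8% to 53.7%), where the Cy5 background was also highest (60 to 92.5, against 42 to 43 elsewhere). R 4.3.3 with the package data.table (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9 were used.

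A limma model with 4 group means and moderated variances gave 5 contrasts: CSP minus CMP, TSP minus TMP, TSP minus CSP, TMP minus CMP and their interaction. P values were adjusted by Benjamini-Hochberg within each contrast, and an adjusted p under 0.05 counted as a call. Recovery was tested on simulated data, with normal noise of each gene's residual SD and the same group sizes, and 200 genes raised or lowered by 2-fold to 16-fold. Of 4-fold changes 76%, 80%, 84%, 60% and 48% were called in the 5 contrasts in the order given, and of 2-fold changes 18%, 14%, 40%, 18% and 6%. The simulated noise was independent and alike in all groups, and the changed genes were drawn at random. In the data TSP 1 and TSP 2 had the profile of the main population, which raised the spread of the genes that separate the populations. For such genes these shares are too high: TSP minus TMP gave 0 calls with all arrays and 3014 without these 2. Adjusted p values of gene lists came from camera in limma, with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted by Benjamini-Hochberg over the 26 lists of a contrast. The test with an estimated correlation is also limited to the residual degrees of freedom of the fit. In fits of few arrays, such as single slides and the main population pairs, a call lost in this test therefore says little about correlation. The lists, written by hand, were: thyroid follicular cell, epithelial, C cell and parathyroid, fibroblast, smooth muscle and pericyte, endothelial, macrophage and pan-leukocyte, lymphocyte, skeletal muscle, adipocyte, erythroid, Schwann and neural, ABC efflux transporter, stem and progenitor associated, epithelial-mesenchymal transition, matrix remodelling, cell cycle, immediate early, interferon response, inflammatory cytokine and chemokine, unfolded protein response, hypoxia and glycolysis, oxidative phosphorylation, ribosomal protein, cholesterol synthesis, and TGF-beta, BMP and Notch target. They name 465 genes, of which 449 were measured, and no gene is in more than 1 list. RNA of the main population also held many of the genes. On all CMP arrays 15 of 17 follicular, 20 of 20 epithelial, 17 of 20 fibroblast and 17 of 20 endothelial genes were well above background. The same held for 16 of 20 macrophage, 11 of 12 ABC transporter and 16 of 17 cholesterol synthesis genes. Which cells of the main population express them was not measured.

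The genes named are, per contrast, the 8 with the largest increase and the 8 with the largest decrease among called genes whose arrays did not overlap between the groups and that were above background on all arrays of at least 1 group; where no gene was called, the 5 with the smallest p are given as values. Up to 4 called members per list and a panel of 21 genes complete the rule, and 1 gene that it names is not reported here. Where a group had no array above background, the fold is a lower bound. The rule, the lists, the comparisons and the alternatives listed next were set before the data were examined. Pairing by replicate number was checked by the correlation of deviations from the group mean. TMP and CMP arrays of the same number gave r of 0.665, 0.744 and 0.809, against at most 0.0926 with another number, and they shared a slide. The other contrasts gave r between -0.263 and 0.464 and were treated as unpaired.

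The results were recomputed with the processed signals of the scanner software, no background subtraction, median centring instead of loess, normalization between arrays, the Cy5 channel alone, the table of values by the authors, no filter or a filter of 9 arrays, outlier spots kept, every probe tested, a variance trend with robust variances, array weights, only the groups compared, replicate number as a block, slide as a block, single slides, and each array left out in turn. The scan day divides the arrays as the slides do. Chosen after seeing the data were fits without TSP 1 and TSP 2, without slide 1, and of the 6 main population arrays with the pairs as a block, some combined with a further alternative. TSP 1 and TSP 2 were kept in their labelled group in the other fits. The position scale uses genes with an unadjusted p under 0.01 and a log2 difference of at least 2 on the CSP and CMP arrays outside slide 1.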

Results

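The thyroid holds a small fraction of cells that keep a fluorescent DNA dye out through membrane pumps, the side population. Gene expression of these cells was compared with that of the other cells, with and without surgical removal of part of the gland. Thyroids of C57BL/6 mice of both sexes were dissociated with enzymes, the cells were held in culture for 2 days, stained with the DNA dye Hoechst and sorted by flow cytometry. The gate for the side population was set with verapamil, a drug that blocks efflux pumps, and cells outside it formed the main population. RNA was measured on 18 arrays in 4 groups: control side population (CSP, 6 arrays), control main population (CMP, 3), side population after partial thyroidectomy (TSP, 6) and main population after partial thyroidectomy (TMP, 3). Each sample was labelled with Cy5 and hybridised together with the same Cy3-labelled reference RNA, pooled from several mouse tissues. Values are log2 ratios of sample over reference. Between 38.8% and 72% of the spots of an array were well above background in Cy5, and the number of arrays limits the precision. The arrays lay on 5 slides. Slide 1 held CSP 1, CSP 2, TSP 1 and TSP 2, and slide 2 held CMP 1 and TMP 1. Slide 3 held CSP 3, CSP 4, TSP 3 and TSP 4. Slide 4 held CSP 5, CSP 6, CMP 2 and TMP 2, and slide 5 held CMP 3, TSP 5, TSP 6 and TMP 3.

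The side population arrays had one profile and the main population arrays another, except that the arrays labelled TSP 1 and TSP 2 had the profile of the main population. Across genes, which are not independent replicates, these 2 arrays correlated with main population arrays at a median r of 0.949 (range 0.889 to 0.962) and with the other side population arrays at a median of 0.695. The other 10 side population arrays correlated with each other at a median of 0.874 and with main population arrays at 0.680. On a scale built from 1029 genes, with 0 at CSP 3 to CSP 6 and 1 at the CMP arrays, TSP 1 lay at 0.997 and TSP 2 at 0.993. TSP 3 to TSP 6 lay between -0.0703 and 0.158, and CSP 1 and CSP 2, on the same slide as TSP 1 and TSP 2, lay at -0.0233 and -0.0258. Both arrays stayed in their labelled group, and values without them are given for the comparisons of TSP. They also enter the spread that the fit shares over the 4 groups. The SEs, p values, estimated correlations and lost calls of CSP against CMP and TMP against CMP below therefore depend on them too. With slide as a block, the differences between CSP and CMP depend on them as well. CSP and CMP share only slide 4, and slides 1, 3 and 5 link them through TSP arrays. Without TSP 1 and TSP 2, 3942 genes differed between CSP and CMP, with a smallest adjusted p of 1.61e-08 (limma), against 3041 and 0.00722 with them. All 95 called genes named for CSP against CMP kept their calls. Leaving them out was chosen after their profiles had been seen, so these values are no independent evidence.

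**Figure D1:**
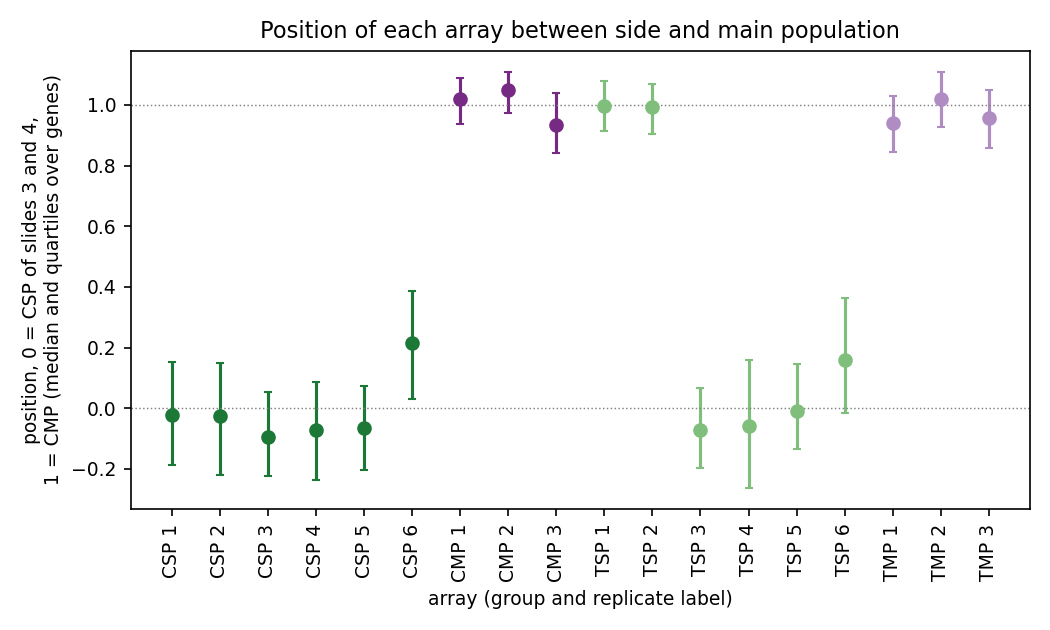
Position of each of the 18 arrays on a scale from side population (0) to main population (1), as the median over 1029 genes, with bars for the quartiles over these genes. The arrays TSP 1 and TSP 2 lie at 0.997 and 0.993, within the range of the 6 main population arrays (0.935 to 1.05).

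The comparison of CSP with CMP asks which genes distinguish the side population in thyroids without surgery. Side population cells had lower expression of thyroid follicular and epithelial genes and higher expression of endothelial, fibroblast and mesenchymal genes than main population cells. Of 20455 genes, 3041 (14.9%) differed (limma, Benjamini-Hochberg adjusted p under 0.05): 1559 were higher and 1482 lower in the side population, and 2614 differed by at least 2-fold (1349 higher, 1265 lower). The highest was Tm4sf1, a membrane protein of the tetraspanin-like L6 family (76-fold, log2 6.25 ± 1.26 SE, adjusted p = 0.00806; 6 CSP against 3 CMP arrays; probe on chromosome 3, 57414702 to 57414761 of mouse build mm7). It was followed by Mctp1, a membrane protein with calcium-binding domains (72.1-fold), Ackr1, the atypical chemokine receptor of venular endothelium (57.7-fold), and Ctla2b and Ctla2a, inhibitors of cysteine proteases (55.5-fold and 46.4-fold). Fabp4, a fatty acid binding protein of adipocytes and capillary endothelium, rose 52.6-fold, the secreted growth factor binding protein Igfbp7 52.2-fold, and matrix Gla protein, Mgp, 51.3-fold. The lowest was Scin, an actin-severing protein, which fell by 5.59 (log2, SE 1.26, 48.2-fold, adjusted p = 0.00949; chromosome 12, 37893261 to 37893320). Tspan1 was 37.5-fold lower, keratin 8 (Krt8) 25.7-fold, Mal2, a protein of apical transport, 25.6-fold, and the epithelial adhesion protein Mpzl2 23.2-fold. The iron reductase Cybrd1 (21.3-fold), the sodium pump subunit Atp1b1 (18.8-fold) and Cdh16, a cadherin of kidney and thyroid (18.2-fold), were also lower. Adjusted p ranged from 0.00799 to 0.00924 for the 8 higher genes and from 0.0094 to 0.0143 for the 8 lower genes (limma), and their CSP and CMP arrays did not overlap.

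With all other arrays kept, 1140 genes differed without CMP 1 and 565 without CMP 2. These counts did not rest on the CMP arrays alone, since TSP 1 and TSP 2 enter the spread shared over the 4 groups. Without TSP 1 and TSP 2, 2667 genes differed when CMP 1 was also left out, and 2688 when CMP 2 was. With TSP 1 and TSP 2 kept, 11 of the 16 genes named above kept their call without CMP 1 and 7 without CMP 2. The loss of CMP 2 ended the calls of Igfbp7 (limma, adjusted p = 0.0515), Scin (0.0529), Krt8 (0.0643) and 6 further lower genes named above. With slide as a block 5785 genes differed (3574 higher, 2211 lower), and within slide 4, with 2 CSP arrays and 1 CMP array, 0 passed in limma after Benjamini-Hochberg adjustment and 4371 had an unadjusted p under 0.05. The slide-block fit gave 4342 genes without TSP 1 and TSP 2 (2570 higher, 1772 lower). Of the calls with all arrays and no block, 51.3% were higher in the side population. This share was 32.5% of 2628 calls with median centring of each array and 39.1% of 460 calls after scaling between arrays (180 higher, 280 lower).

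Of 17 measured thyroid follicular genes, 12 fell in the side population and 0 rose, both over all genes and adjusted over the list alone. The list mean was -2.22 (log2; camera with a preset correlation of 0.01, adjusted p = 4.5e-10, and adjusted p = 0.305 with an estimated correlation), and it was lower on all 6 CSP arrays than on any CMP array. The thyrotropin receptor Tshr had a log2 ratio of 0.13 ± 0.50 (SD, n = 6) in CSP and 3.11 (SD 0.505, n = 3) in CMP, a 7.88-fold decrease (SE of the log2 difference 0.669, limma, adjusted p = 0.00949). The deiodinases Dio1 (9.36-fold, adjusted p = 0.0094) and Iyd (8.82-fold, 0.0134) and the thyroid transcription factors Pax8 (7.72-fold, 0.0138), Nkx2-1 (6.98-fold, 0.0212) and Foxe1 (6.93-fold, 0.00857) fell as well, by limma. Of the 6 CSP arrays, Foxe1 was well above background on 1, Tshr on 3, and Pax8 and Nkx2-1 on 4, so the size of these folds is uncertain. On all CSP arrays 4 of the 17 follicular genes were well above background. Thyroglobulin, Tg, the precursor of thyroid hormone, did not pass (log2 4.10 ± 0.93 in CSP, 5.28 ± 0.82 in CMP, adjusted p = 0.27, limma), and the sodium iodide symporter Slc5a5 was well above background on 0 CSP and 2 CMP arrays. CSP 6 stood apart in this group, with a follicular list mean of 1.12 where the next CSP array had -0.25. Leaving out CMP 1 ended the calls of Iyd (0.0616), Tshr (0.052), Pax8 (0.0786), Nkx2-1 (0.0874) and Cdh16 (0.0588). Without CMP 2 those of Dio1 (0.0515), Iyd (0.0605), Pax8 (0.0568), Nkx2-1 (0.07), Foxe1 (0.0514) and Cdh16 (0.0515) were lost, and without CMP 3 that of Nkx2-1 (0.0532).

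Of 20 epithelial genes, 19 fell and 0 rose (19 and 0 adjusted over the list alone), with a list mean of -2.84 (camera, adjusted p = 1.32e-12, and adjusted p = 0.305 with an estimated correlation). Keratin 18 (Krt18) was 15.5-fold lower, E-cadherin (Cdh1) 12.6-fold, keratin 7 (Krt7) 9.78-fold and the epithelial adhesion molecule Epcam 7.06-fold (limma, adjusted p from 0.0117 to 0.0277). The calls of Krt18, Cdh1 and Epcam were lost without CMP 1 (adjusted p = 0.0547, 0.0663 and 0.0691) or CMP 2 (0.0606, 0.0594 and 0.0643), and that of Krt7 without any of 5 arrays (CSP 1, CSP 2 and the 3 CMP arrays, up to 0.104). The follicular mean was -2.37 with slide as a block and -1.81 within slide 4, and the epithelial mean -2.94 and -2.05.

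Endothelial and connective tissue genes showed the opposite direction. Of 20 endothelial genes, 18 rose and 0 fell (19 and 0 adjusted over the list alone), with a list mean of 3.13 (camera, adjusted p = 2.35e-12). Von Willebrand factor, Vwf, was 34.9-fold higher, endomucin, Emcn, 25.7-fold, VE-cadherin, Cdh5, 19.1-fold, and the junction protein Pecam1 5.74-fold (limma, adjusted p between 0.00806 and 0.00972). Of 20 fibroblast genes, 15 rose and 0 fell (20 and 0 adjusted over the list alone), with a mean of 2.84 (camera, adjusted p = 6.56e-11). They included the platelet-derived growth factor receptors Pdgfrb (29.8-fold) and Pdgfra (12.5-fold) and the matrix proteoglycans Lum (24.9-fold) and Dcn (19.2-fold). Collagen 1, Col1a1, did not pass (log2 difference 2.63 ± 0.93 SE, limma, adjusted p = 0.0643). Of 14 smooth muscle and pericyte genes, 4 rose and 2 fell (7 and 2 adjusted over the list alone; mean 1.03, camera, adjusted p = 0.0162), with the pericyte proteoglycan Cspg4 13.9-fold higher. Without CMP 2 the calls of Cdh5 (adjusted p = 0.0515), Pecam1 (0.0556) and Dcn (0.0578) were lost. With an estimated correlation the adjusted p was 0.305 for the endothelial and fibroblast lists and 0.53 for the smooth muscle list, which also lost its call after scaling between arrays (0.0684). The endothelial mean was 3.97 with slide as a block and 3.54 within slide 4, the fibroblast mean 3.57 and 3.21, and the smooth muscle mean 1.43 and 1.21. Markers of other cell types did not move alike: of 20 macrophage and leukocyte genes 1 rose and 3 fell (1 and 4 adjusted over the list alone), with a mean of -0.64 (camera, adjusted p = 0.00339, and adjusted p = 0.53 with an estimated correlation; slide block -0.36, within slide 4 -0.575; adjusted p = 0.189 after scaling between arrays). Over 37 alternatives the adjusted p ranged from 0.00114 to 0.0938 for the smooth muscle list and from 1.85e-05 to 0.189 for the macrophage list. The protease Ctss of antigen-presenting cells fell 12.9-fold (limma, adjusted p = 0.00959; 0.0556 without CMP 2), and the pan-leukocyte marker Ptprc did not pass (log2 difference -0.59, limma, adjusted p = 0.333).

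**Figure D2:**
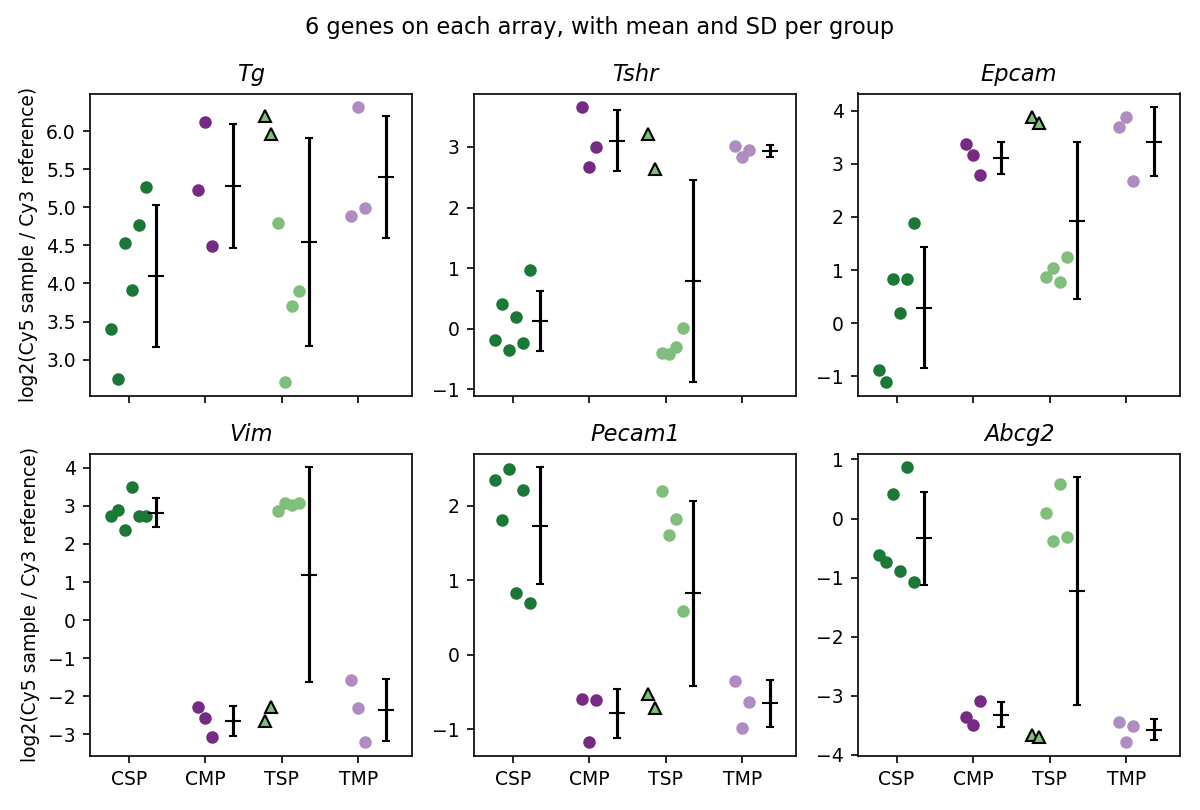
Log2 ratio of sample over reference of 6 genes of a fixed panel on each of the 18 arrays, by group, with mean and SD. Triangles with a black edge are TSP 1 and TSP 2, which lie beside the main population arrays for genes such as Epcam, Vim and Abcg2.

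Genes of mesenchymal cells and of tissue remodelling were higher in the side population. Of 16 genes linked to the epithelial-mesenchymal transition, 13 rose and 0 fell (13 and 1 adjusted over the list alone; mean 2.61, camera, adjusted p = 1.8e-08, and adjusted p = 0.305 with an estimated correlation; slide block 3.1, within slide 4 2.68). Without slide 1, a fit chosen after seeing the data, this list held with an estimated correlation (camera, adjusted p = 0.00966). The follicular, epithelial, fibroblast, endothelial and cholesterol synthesis lists then had 0.115 each and did not hold. That fit leaves out CSP 1 and CSP 2 as well as TSP 1 and TSP 2. Vimentin, Vim, the intermediate filament of mesenchymal cells, was 44.2-fold higher (log2 5.47 ± 1.08 SE, limma, adjusted p = 0.00799). The transcription factors Foxc2 (24.4-fold) and Twist1 (12.5-fold) and the gelatinase Mmp9 (16.8-fold) rose with it. Of 16 matrix remodelling genes, 9 rose and 3 fell (11 and 3 adjusted over the list alone; mean 1.46, camera, adjusted p = 0.00746, and adjusted p = 0.305 with an estimated correlation). The secreted protein osteopontin, Spp1, was 42.6-fold and stromelysin, Mmp3, 40.7-fold higher, whereas of the plasminogen activators Plat was 11.3-fold higher and Plau 7.99-fold lower (limma, adjusted p up to 0.0156). The Spp1 call was lost without CMP 1 (adjusted p = 0.068) or CMP 2 (0.0594). Within slide 4 the matrix mean was 1.69, with slide as a block it was 1.74 without a call (adjusted p = 0.0626), and the call was also lost after scaling between arrays (0.345). Over 37 alternatives the adjusted p of this list ranged from 0.000504 to 0.345.

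Efflux pumps and genes associated with stem cells formed a separate question, since the gate itself selects cells that export the dye. Of 12 measured ABC transporter genes, 6 rose and 2 fell (7 and 2 adjusted over the list alone; mean 1.34, camera, adjusted p = 0.00746, and adjusted p = 0.339 with an estimated correlation; slide block 1.75, within slide 4 1.57). Abcg2, a pump that exports the dye and marks side populations of many tissues, was 7.90-fold higher (log2 -0.34 ± 0.79 in CSP, -3.32 ± 0.21 in CMP, SE 0.786, adjusted p = 0.0172; chromosome 6, 58658701 to 58660383). The P-glycoprotein genes Abcb1a (9.46-fold, adjusted p = 0.0107; chromosome 5, 8785623 to 8785682) and Abcb1b (8.31-fold, 0.0108) and Abcc4 (6.81-fold, 0.011) were higher too, by limma. Without CMP 2 the calls of Abcg2 (adjusted p = 0.0722), Abcb1a (0.0556), Abcb1b (0.0582) and Abcc4 (0.0529) were lost, and without CMP 1 those of Abcg2 (0.0666) and Abcc4 (0.0515). Of 17 stem and progenitor genes, 1 rose and 3 fell (2 and 4 adjusted over the list alone), and the list was not called (mean -0.026, camera, adjusted p = 0.559). Cd34, expressed by blood progenitors and by endothelium, was 19.1-fold higher, and the progenitor transcription factor Sox9 was 6.53-fold lower (limma, adjusted p = 0.00924 and 0.0105; Sox9 0.052 without CMP 2). The pluripotency factor Pou5f1 (log2 difference -0.049, limma, adjusted p = 0.922) and the stem cell antigen Ly6a (1.49, 0.0793) did not pass.

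Genes of cholesterol synthesis were lower in the side population: 13 of 17 fell and 0 rose (15 and 0 adjusted over the list alone; mean -1.65, camera, adjusted p = 6.74e-11, and adjusted p = 0.305 with an estimated correlation; slide block -1.59, within slide 4 -1.29). The sterol oxidase Msmo1 was 7.96-fold lower and squalene epoxidase, Sqle, 5.03-fold (limma, adjusted p = 0.00799 each). Inflammatory genes went both ways: of 21 cytokines, chemokines and related genes 9 rose and 7 fell, over all genes and adjusted over the list alone, and the list mean of 0.29 was not called (camera, adjusted p = 0.796). Interleukin 6, Il6, was 14.9-fold and the chemokine Cxcl5 13.8-fold higher, and the interleukin 1 receptor antagonist Il1rn was 11.7-fold lower (limma, adjusted p = 0.0142, against 0.0671 without CMP 1 and 0.0596 without CMP 2). Smaller shifts were called by camera for targets of TGF-beta, BMP and Notch signalling (mean 0.92; 5 rose and 1 fell of 19, 8 and 2 adjusted over the list alone; adjusted p = 0.00933) and the unfolded protein response (0.70; 4 and 0 of 16, 6 and 0 adjusted over the list alone; 0.00446). Camera also called ribosomal proteins (0.63; 4 and 0 of 24, 5 and 0 adjusted over the list alone; 0.000506), C cell and parathyroid genes (1.13; 3 and 0 of 13, 7 and 0 adjusted over the list alone; 0.014) and immediate early genes (0.63; 3 and 0 of 20, 7 and 2 adjusted over the list alone; 0.04). The cell cycle list shifted down (mean -0.41; 0 rose and 2 fell of 31, both ways of adjusting; camera, adjusted p = 0.00689). None of these 6 calls held with an estimated correlation. The adjusted p was then 0.46, 0.319, 0.319, 0.53, 0.53 and 0.611 in the order named. Without CMP 3 the calls of the cell cycle (camera, adjusted p = 0.194), Notch (0.0747), C cell (0.0578) and immediate early lists (0.307) were lost, and the last also without CSP 3 (0.0863) or CMP 2 (0.0851). With slide as a block the means were 0.96, 0.70, 0.76, 1.45, 0.72 and -0.71, of which the ribosomal and cell cycle lists kept their calls, and within slide 4 they were 0.71, 0.47, 0.53, 1.04, 0.67 and -0.47. Over 37 alternatives the adjusted p reached 0.154, 0.159, 0.028, 0.15, 0.307 and 0.194 at its highest.

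The other lists were not called by camera in CSP against CMP: hypoxia and glycolysis (mean 0.54; 6 rose and 0 fell of 17, 6 and 1 adjusted over the list alone; adjusted p = 0.0539), oxidative phosphorylation (0.838), interferon response (0.718), adipocyte (0.35), erythroid (0.319), Schwann and neural (0.299), lymphocyte (0.768) and skeletal muscle (0.56). The adipocyte list was called higher with slide as a block (mean 1.43, 7 of 10 members higher, adjusted p = 0.00118, and adjusted p = 0.44 with an estimated correlation) and within slide 4 with its 1 CMP array (1.15, 0.00796, and 0.789 with an estimated correlation). The hypoxia list was called in 16 of 37 alternatives, among them within slide 4 (0.76, 0.028, and 0.789 with an estimated correlation) and without TSP 1 and TSP 2 (0.0282 and 0.373). Over 37 alternatives their adjusted p ranged from 0.00109 to 0.832 and from 0.0141 to 0.402. Among their members the oxygen sensor Egln3 was 6.58-fold higher and the receptor Erbb3 of neural crest and epithelial cells 8.64-fold lower (limma, adjusted p = 0.00931 and 0.0139). Without CMP 2 both calls were lost (adjusted p = 0.052 and 0.057), that of Erbb3 also without CMP 1 (0.0615).

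The comparison of TSP with TMP asks the same question after partial thyroidectomy. Follicular and epithelial gene lists were again lower and endothelial and fibroblast lists higher in the side population, although with all arrays 0 single genes passed. In limma with Benjamini-Hochberg adjustment over 20455 genes, 0 genes differed, 2796 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0555. That gene was Duox1, an oxidase that makes the hydrogen peroxide for thyroid hormone synthesis (log2 -1.34 ± 0.20 SE). It was followed by 4932438H23Rik, not well above background on any TSP array (at least 1.89-fold lower, adjusted p = 0.138), the actin-binding peptide Tmsb10 (-1.41, 0.159), interleukin 1 beta, Il1b (-2.89, 0.159), and the chemokine Ccl4 (-3.06, 0.186). Other fits gave 1 gene without background subtraction, without a filter on dim probes or with a variance trend, 754 with array weights, 236 with slide as a block (168 higher, 68 lower) and 238 within slide 5, which holds 2 TSP arrays and 1 TMP array, so that the lone TMP array is assumed to vary as the TSP arrays do. Leaving out TSP 1 gave 509 genes, leaving out TSP 2 gave 615, and leaving out CSP 2 or CSP 6 gave 1. Without both TSP 1 and TSP 2, 3014 genes differed (1582 higher, 1432 lower), and 2640 of them by at least 2-fold.

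Camera called 16 of the 26 lists between TSP and TMP with all arrays, and none held with an estimated correlation. The follicular mean was -1.65 (adjusted p = 7.19e-12, and adjusted p = 0.258 with an estimated correlation) and the epithelial mean -1.74 (9.32e-11, 0.296). The means were 2.2 for fibroblast genes (3.39e-14, 0.258), 1.83 for endothelial genes (4.3e-11, 0.296) and 1.71 for mesenchymal transition genes (7.49e-10, 0.258), again with the second adjusted p from an estimated correlation. Adjusted over the list alone, 12 of 17 follicular and 12 of 20 epithelial genes fell, and 17 of 20 fibroblast, 15 of 20 endothelial and 11 of 16 transition genes rose, against 0 over all genes. TSP 3 to TSP 6 had follicular means from -0.71 to 0.019, and TSP 1 and TSP 2, at 2.04 and 2, lay within the range of the main population arrays (1.93 to 2.23). The other 4 means were beyond every TMP array on 4 of 6 TSP arrays. With slide as a block these 5 means, in the order named, were -1.54, -1.48, 2.72, 2.35 and 2.05, and within slide 5 they were -2.17, -2.33, 3.27, 2.86 and 2.59. Without TSP 1 and TSP 2 they were -2.41, -2.7, 3.23, 2.85 and 2.57.

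Further lists were higher in TSP by camera with all arrays: matrix remodelling (mean 1.07, adjusted p = 0.00069), ABC transporters (0.93, 0.00228), smooth muscle (0.68, 0.0143), adipocyte (0.65, 0.0486), TGF-beta and Notch targets (0.60, 0.0138), hypoxia (0.52, 0.00119), the unfolded protein response (0.43, 0.0043) and ribosomal proteins (0.33, 0.00647). Lower were cholesterol synthesis (-0.68, 9.22e-05), macrophage (-0.63, 3.33e-05) and cell cycle genes (-0.51, 9.22e-05). With an estimated correlation the adjusted p of these 11 lay between 0.258 and 0.514. Adjusted over the list alone, 7 matrix genes rose and 3 fell, 4 smooth muscle genes rose and 1 fell, 3 ABC genes, 3 hypoxia genes, 1 adipocyte gene and 1 unfolded protein gene rose, 4 macrophage genes fell, and 0 members of the other 4 lists passed. Leaving out TSP 6 ended the calls of the adipocyte (adjusted p = 0.295) and smooth muscle lists (0.11), and TSP 3 that of the TGF-beta and Notch list (0.061). Leaving out TMP 3 ended those of the same list (0.152) and the unfolded protein list (0.0757), TMP 2 that of the adipocyte list (0.439) and TMP 1 that of the ribosomal list (0.05). The adipocyte call was also lost without TSP 5 (0.123) and without any of CSP 1, CSP 4, CSP 5, CSP 6, CMP 1 and CMP 3 (0.0503 to 0.0538). With slide as a block the unfolded protein and the TGF-beta and Notch lists lost their calls (adjusted p = 0.0915 each) and the erythroid list was called (mean 0.31, 0.0281, and adjusted p = 0.424 with an estimated correlation). Over 37 alternatives the highest adjusted p was 0.721 for the adipocyte, 0.271 for the smooth muscle, 0.152 for the Notch, 0.138 for the ribosomal and 0.0915 for the unfolded protein list. The cytokine list was not called (camera, adjusted p = 0.176), with 5 members higher and 7 lower adjusted over the list alone.

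Without TSP 1 and TSP 2 camera called the same 16 lists, with larger means for most. They were 1.58 for matrix remodelling (10 members higher and 2 lower over all genes), 1.45 for ABC transporters (7 and 1), 1.22 for smooth muscle (7 and 1), 1.01 for adipocyte (2 and 0), 1.01 for TGF-beta and Notch targets (8 and 1), 0.71 for hypoxia (5 and 0), 0.65 for the unfolded protein response (5 and 1) and 0.47 for ribosomal proteins (3 and 0). The means were -1.02 for cholesterol synthesis (0 and 6), -0.84 for macrophage (1 and 6) and -0.49 for cell cycle genes (0 and 2). The adjusted p of these 11 lists lay between 2.42e-05 and 0.0176, and with an estimated correlation between 0.0711 and 0.754.

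Without TSP 1 and TSP 2, single genes separated TSP from TMP much as in controls. Of the follicular genes 12 of 17 fell, of the epithelial genes 18 of 20, and 20 of 20 fibroblast, 18 of 20 endothelial and 13 of 16 transition genes rose (limma over all genes; 15, 19, 20, 18 and 13 adjusted over the list alone). Under an estimated correlation the follicular (camera, adjusted p = 0.0411) and transition lists (0.00269) held, and the epithelial (0.0889), fibroblast (0.0634) and endothelial lists (0.0711) did not. Without slide 1, which leaves the same TSP and TMP arrays, the follicular call was lost (0.0603) and the transition call held (0.00561). Igfbp7 was 80.1-fold higher (log2 6.32 ± 0.40 SE, adjusted p = 4.29e-08, limma), Tm4sf1 73.4-fold, Mmp3 67.5-fold, Mgp 67.2-fold, Spp1 66.8-fold, Pdgfrb 48.1-fold, Fabp4 47.3-fold and Mctp1 47.2-fold. Tspan1 was 49.9-fold lower (log2 -5.64 ± 0.80 SE, adjusted p = 0.000104, limma), Scin 46.5-fold, Cybrd1 26.7-fold, Atp1b1 23.9-fold, the microtubule-associated protein Clip4 23.4-fold, Mal2 23.2-fold and Mpzl2 23.1-fold. Abcg2 was 11.9-fold (adjusted p = 1e-05) and Abcb1b 13.1-fold higher (4.71e-08), Il6 13.5-fold higher, and Il1b at least 12.9-fold lower (5.87e-07), all by limma. In this fit 3942 genes differed between CSP and CMP. Of these, 1346 higher and 1221 lower genes were shared with the TSP against TMP calls (85.1% and 85.3% of the TSP calls, 0 in opposite directions). Independent lists would share 161.5 and 129.8. The lists are not independent, since both contrasts come from the same fit and share the estimated spread of each gene. The log2 differences of the 2 comparisons correlated across genes, which are not independent, at r = 0.93 without these arrays and 0.91 with them, where 0 calls were shared.

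**Figure D3:**
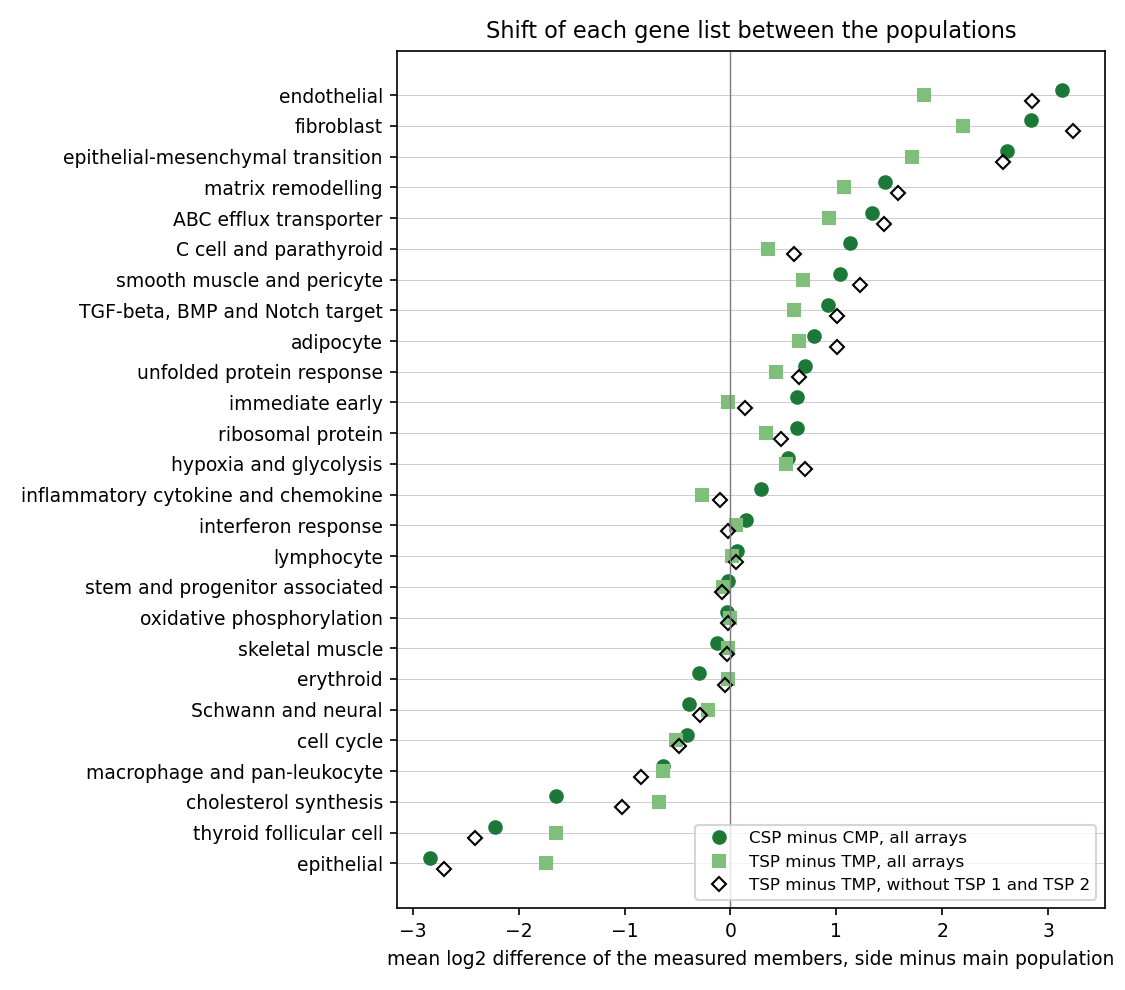
Mean log2 difference between side and main population for each of the 26 gene lists, with circles for CSP against CMP and squares for TSP against TMP with all arrays, and open diamonds for TSP against TMP without TSP 1 and TSP 2. Follicular and epithelial lists lie at -2.22 and -2.84 and endothelial and fibroblast lists at 3.13 and 2.84 in the control comparison.

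The comparison of TSP with CSP asks what changed in the side population after surgery. No single gene passed, and the calls of the follicular, epithelial, endothelial and mesenchymal transition lists were lost without TSP 1 and TSP 2. Limma with Benjamini-Hochberg adjustment called 0 of 20455 genes, with 1857 at an unadjusted p under 0.05 and a smallest adjusted p of 0.356. The smallest p values belonged to 2 array transcripts without a gene symbol, NAP028025-1 (log2 -0.98) and NAP030857-1 (-1.17), and to the tRNA methyltransferase Trmt1l (0.87), the kinase Mapk9 (0.93, another probe with the opposite sign) and the retinoic acid binding protein Crabp1 (-2.21, SE 0.458), all at an adjusted p = 0.356. Other fits called 1 gene with the replicate block, 899 with slide as a block (353 higher, 546 lower), 8315 within slide 1, which holds TSP 1 and TSP 2 (3523 higher, 4792 lower), and 0 within slide 3. Without TSP 3 there was 1 call and without TSP 4 there were 3. Without TSP 1 and TSP 2 there were 0 calls and 697 genes at an unadjusted p under 0.05, or 18 calls (10 higher, 8 lower) with slide as a block.

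With all arrays camera called epithelial (mean 1.1, adjusted p = 2.83e-09), follicular (0.59, 0.000839), cholesterol synthesis (0.39, 0.000882), macrophage (0.38, 0.000529) and interferon response genes (0.33, 0.000532) higher in TSP than in CSP. Endothelial (-1.22, 1.88e-08), mesenchymal transition (-0.82, 0.000839), fibroblast (-0.63, 0.00518), C cell (-0.62, 0.00804) and ribosomal protein genes (-0.33, 0.000529) were lower. The adjusted p with an estimated correlation was 0.692 or 0.733 for each. Of the members, 0 passed over all genes or, except 1 C cell gene, adjusted over the list alone. Without TSP 1 and TSP 2 the follicular mean was -0.17 (camera, adjusted p = 0.17), the epithelial mean 0.14 (0.223), the endothelial mean -0.20 (0.115), the transition mean 0.037 (0.729), the macrophage mean 0.17 (0.098) and the cholesterol mean 0.051 (0.62), and the fibroblast list was higher, at 0.40 (0.0035, and adjusted p = 0.907 with an estimated correlation). Within slide 1 the follicular, epithelial, fibroblast and endothelial means were 2.35, 4.04, -3.21 and -3.45. Within slide 3 they were -0.10, -0.28, 1.1 and -0.12, and with slide as a block 0.84, 1.46, -0.86 and -1.55. Leaving out TSP 1 or TSP 2 ended the calls of the follicular (adjusted p = 0.0604 and 0.0619) and fibroblast lists (0.334 and 0.268), leaving out CSP 2 that of the fibroblast list (0.0778), and leaving out CSP 4 (0.135) or TSP 3 (0.075) that of the C cell list. The C cell call was also lost with slide as a block (mean -0.73, adjusted p = 0.2), where lymphocyte (-0.29, 0.0377) and adipocyte lists (-0.54, 0.029) were called lower, with an adjusted p = 0.755 each with an estimated correlation. Without slide 1 the follicular (-0.28, 0.0335) and epithelial lists (-0.37, 0.0109) were called lower and the fibroblast list higher (0.65, 2.28e-06), each opposite to the call with all arrays, and the macrophage list was called higher (0.36, 0.000587), with an adjusted p between 0.544 and 0.599 with an estimated correlation. The macrophage and ribosomal lists changed direction after scaling between arrays (-0.645 and 0.21). Over 38 alternatives the highest adjusted p of the 10 lists lay between 0.399 and 0.968.

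The interferon list was the 1 list that camera called higher in TSP both with all arrays and without TSP 1 and TSP 2 (mean 0.26, adjusted p = 0.0035, and adjusted p = 0.907 with an estimated correlation). Its mean was 0.71 within slide 3, -0.033 within slide 1 and 0.39 with slide as a block, and the call was lost after scaling between arrays (adjusted p = 0.0804). C cell genes (-0.37, 0.0447) and ribosomal protein genes (-0.185, 0.0208) were also lower without these 2 arrays, and smooth muscle (0.37, 0.000973) and ABC transporter genes (0.21, 0.0208) were higher, by camera, each with an adjusted p = 0.907 with an estimated correlation. Without slide 1 the smooth muscle (0.32, 0.00509), ABC (0.18, 0.0335) and C cell lists (-0.62, 0.00324) were called as well, with an adjusted p = 0.544 each with an estimated correlation, and the ribosomal list was not (-0.125, 0.283). Within slide 1 the smooth muscle (-1.15, 0.0021) and ABC lists (-1.29, 0.00944) were lower (0.434 and 0.419 with an estimated correlation), and with all arrays they were not called (adjusted p = 0.733 and 0.502), within a range over 38 alternatives from 0.000973 to 0.904 and from 0.00944 to 0.991.

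The comparison of TMP with CMP asks what changed in the main population after surgery. No single gene passed without pairing. As lists, by camera with a preset correlation, cholesterol synthesis was shifted down and interferon response, immediate early, cytokine and macrophage genes were shifted up, each by less than 2-fold on average, and 4 of these 5 calls were lost with an estimated correlation. TMP and CMP arrays of the same number shared a slide and deviated together, so the values with the pairs as a block are given beside the others. The mean of the 17 cholesterol synthesis genes was -0.58 (log2; median -0.60; camera, adjusted p = 1.02e-16, and adjusted p = 0.0611 with an estimated correlation; paired 1.03e-22 and 0.79). It was lower on all 3 TMP arrays than on any CMP array. The mean was -0.60, -0.77 and -0.38 within slides 2, 4 and 5, where 16, 17 and 16 of the 17 genes lay below 0, and -0.58 with slide as a block. Examples, chosen after their values had been seen, were HMG-CoA synthase, Hmgcs1, at the entry of the pathway (log2 -0.95 ± 0.49 SE), Msmo1 (-0.91) and the reductase Dhcr7 of the last step (-0.90). With the preset correlation the adjusted p ranged from 9.98e-24 to 8.6e-08 over 37 alternatives. Over all genes 0 members passed, and adjusted over the list alone 0 passed, or 15 in the paired fit.

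The interferon response list had a mean of 0.42 (camera, adjusted p = 3.02e-10, and adjusted p = 0.115 with an estimated correlation; paired 1.75e-12), with 0.42, 0.75 and 0.10 within slides 2, 4 and 5. Its largest differences, chosen after they had been seen, were those of the antiviral genes Iigp1 (log2 1.08, SE 0.755), Ifit3 (0.95) and Ifit1 (0.93). The mean was 0.36 for the immediate early list (6.75e-07, and 0.196 with an estimated correlation; paired 4.98e-11; 0.41, 0.495 and 0.18 within the slides) and 0.37 for the macrophage list (1.36e-08, and 0.425 with an estimated correlation; paired 1.11e-10; 0.755, 0.04 and 0.32). It was 0.36 for the cytokine and chemokine list (0.000103, and 0.0185 with an estimated correlation; paired 2.21e-09; 0.31, 0.22 and 0.54), and lipocalin 2, Lcn2, an antibacterial protein, had the largest difference among them (log2 1.27 ± 0.57 SE, chosen after it had been seen). With slide as a block these 4 means were the same and all were called. Of the 57 list calls of the 5 comparisons only this cytokine call held with an estimated correlation, and there its adjusted p was 0.116 with slide as a block and 0.79 in the paired fit. The paired adjusted p of the other 3 was between 0.79 and 0.853. The estimated correlation of the cytokine list was 0.0087, below the preset 0.01, so a higher correlation does not account for its weaker call. In the paired fit, with few residual degrees of freedom, no list had an adjusted p under 0.79 in this test. It cannot tell there whether the calls hold. Adjusted over the list alone, 0 members of the 4 lists passed, or 6, 8, 3 and 9 in the paired fit. Leaving out CMP 3 ended the calls of the immediate early (adjusted p = 0.242) and cytokine lists (0.144), and leaving out TMP 1 that of the immediate early list (0.589). Over 37 alternatives the adjusted p of the 4 lists reached 0.00224, 0.589, 0.0408 and 0.144.

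Among single genes limma with Benjamini-Hochberg adjustment called 0 of 20455 between TMP and CMP, with 24 at an unadjusted p under 0.05, and the 5 with the smallest p were LOC671351 (log2 1.68), BC005655 (1.76), Irg1, an enzyme of itaconate synthesis (1.14), Dcpp2 (1.09) and the keratin Krt87 (0.97), all at an adjusted p of 1. Without any difference a share of about 0.05 of the genes would have an unadjusted p under 0.05, far more than 24. The spread of this fit, shared over the 4 groups and without the pairs, was thus too large for this contrast. The SE of Vim, for example, was 1.25 here and 0.18 with the pairs as a block. The 0 calls are therefore no evidence that little changed. With the pairs as a block on the 6 main population arrays, 6 genes passed and 1223 had an unadjusted p under 0.05. They were BC005655 and LOC671351 (adjusted p = 0.00112 each), the secreted proteins Spink8 (0.0263), Dcpp1 (0.0263) and Dcpp2 (0.0309), all higher, and Fabp5, a fatty acid binding protein, which fell by 1.21 (log2, SE 0.159, adjusted p = 0.0182, limma). Leaving out pair 1, 2 or 3 gave 7, 29 or 332 calls. In that fit C cell (mean 0.16, camera, adjusted p = 0.0357) and smooth muscle genes (0.17, 0.0197) were also called higher, with 0.863 and 0.853 as the adjusted p with an estimated correlation. Follicular genes (mean 0.018), epithelial genes (-0.00085, with a median of 0.048), fibroblast genes (0.0053, median -0.034) and endothelial genes (0.082) were not called by camera.

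**Figure D4:**
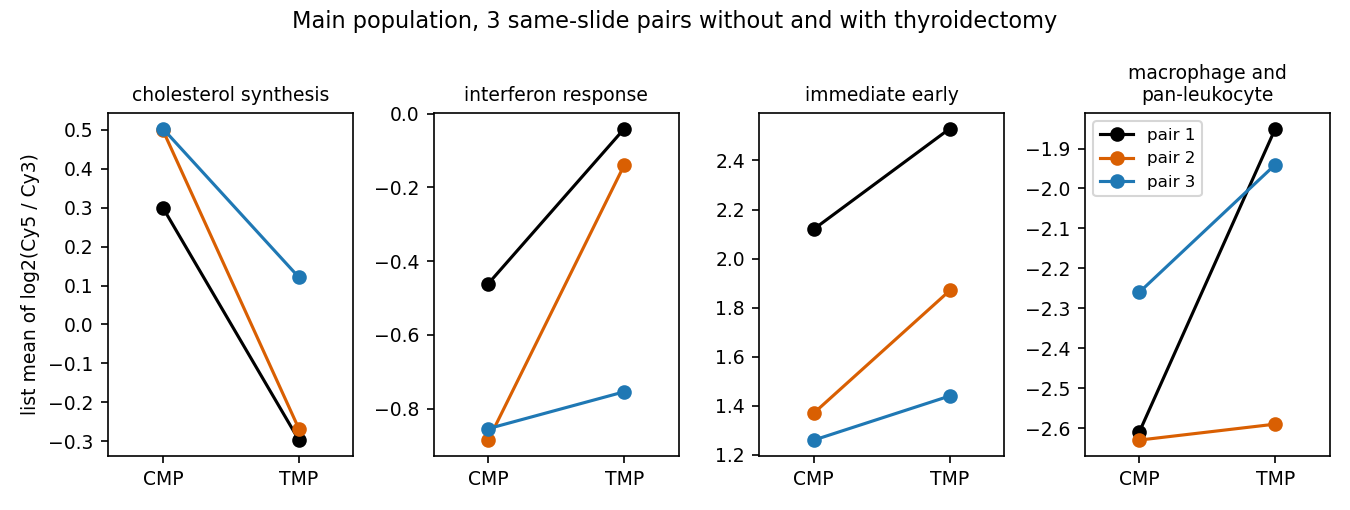
Mean log2 ratio over the members of 4 gene lists on the CMP and TMP arrays, with lines joining the 3 pairs of arrays that share a slide. The cholesterol synthesis mean is lower in TMP in each pair, by -0.60, -0.77 and -0.38, and the interferon mean is higher in each, by 0.42, 0.75 and 0.10.

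The interaction asks whether the change after surgery differed between the populations, as TSP minus CSP less TMP minus CMP. Limma with Benjamini-Hochberg adjustment called 0 of 20455 genes, with 219 at an unadjusted p under 0.05. Without TSP 1 and TSP 2 it called 0 (121 unadjusted), or 1 gene when background subtraction was also left out. Both unadjusted counts lay far below a share of 0.05 of the genes, so the 0 calls are no evidence against a difference. The smallest p values were those of Gpnmb, a membrane glycoprotein of macrophages and pigment cells (log2 -2.01 ± 0.55 SE), Crabp1 (-2.50), the ADP-ribosyltransferase Parp16, the transcript AK013903 (-1.33) and LOC671351 (-1.41), each at an adjusted p of 1. Camera called 10 of the 26 lists, of which cholesterol synthesis had the smallest adjusted p (mean 0.97, adjusted p = 4.55e-13, and adjusted p = 0.183 with an estimated correlation). The list mean was -0.58 in TMP against CMP and 0.39 in TSP against CSP, and 0 members passed in either or in the interaction. Without TSP 1 and TSP 2 this mean was 0.63 (camera, adjusted p = 7.91e-09, and adjusted p = 0.259 with an estimated correlation), and with slide as a block 1.04 (9.88e-11 and 0.743), within a range of adjusted p from 1.04e-16 to 1.89e-05 over 35 alternatives. Median, mean and test differed in sign only for lists that were not called: oxidative phosphorylation and erythroid genes in TSP against TMP, stem and adipocyte genes in TSP against CSP, epithelial, fibroblast, lymphocyte and skeletal muscle genes in TMP against CMP, and adipocyte, stem, cell cycle and hypoxia genes in the interaction.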

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

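The tests of TSP 1 and TSP 2 below, and the fits without them, were chosen after the result was seen; the search for samples far from their group and the interaction tests were planned. In 98 groups of array values, 3 had an array far from the others, where chance gives about 1 in 20 groups. CSP 6 had the highest Pax8 (1.7, nearest other array 0.544) and follicular list mean (1.12, nearest -0.25) of the CSP arrays, and TSP 3 had the lowest Calca of the TSP arrays (1.5, nearest 3.63).

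For 10 gene lists the change after surgery differed between side and main population by the interaction test (camera). The mean differences were 0.576 for follicular genes (adjusted p = 0.00856; without TSP 1 and TSP 2 -0.188, 0.176), 1.1 for epithelial genes (2.39e-07; 0.143, 0.341), -0.639 for fibroblast genes (0.0179; 0.391, 0.0146), -1.3 for endothelial genes (2.39e-07; -0.283, 0.0786) and -0.895 for mesenchymal transition genes (0.0024; -0.0341, 0.859). They were -0.777 for C cell genes (0.00191; -0.527, 0.0093), -0.652 for immediate early genes (5.75e-05; -0.493, 6.04e-05), -0.558 for cytokine genes (0.016; -0.389, 0.00477), -0.295 for ribosomal protein genes (0.00616; -0.153, 0.085) and 0.971 for cholesterol synthesis genes (4.55e-13; 0.633, 7.91e-09). With an estimated correlation the adjusted p in the order named was 0.841, 0.62, 0.841, 0.62, 0.706, 0.62, 0.55, 0.183, 0.656 and 0.183, and without TSP 1 and TSP 2 or with slide as a block it lay between 0.259 and 0.958 for these lists. With slide as a block the means were 0.825, 1.46, -0.858, -1.63, -1.06, -0.891, -0.598, -0.548, -0.422 and 1.04, and the C cell (adjusted p = 0.0724) and cytokine lists (0.151) lost their calls. Left out singly, CMP 2 (adjusted p = 0.0709), TSP 1 (0.226), TSP 2 (0.248) or TMP 3 (0.0671) ended the follicular call, and CSP 2 (0.153), CSP 6 (0.0735), CMP 2 (0.108), TSP 1 (0.447), TSP 2 (0.402) or TMP 1 (0.203) the fibroblast call. The immediate early call was lost without TMP 1 (0.0662), the cytokine call without CMP 3 (0.141), TSP 5 (0.0513) or TSP 6 (0.0519), and the ribosomal call without CMP 1 (0.137) or TMP 3 (0.0652). Over 35 alternatives the highest adjusted p was 1.89e-05 for cholesterol synthesis genes and between 0.403 and 0.996 for the other 9 lists.

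The arrays TSP 1 and TSP 2 resembled the main population. An effect of slide 1 as a whole is argued against by CSP 1 and CSP 2 on the same slide, whose median position was -0.0245, and an exchange of labels with main population arrays by the finding that 0 main population arrays lay under 0.5. A change of the side population after surgery in every animal is argued against by TSP 3 to TSP 6, with a median position of -0.0334. Main population RNA under these labels, without a partner, may explain the profile: the median position of both arrays was 0.995, within the range of the main population arrays (0.935 to 1.05). That position restates the likeness for which the arrays were singled out, so it adds no evidence for this explanation. A response of the side population in some animals only, or a sort that took in main population cells, stays open and was not tested, since no array was labelled by animal or by the purity of the sort.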

How the results depend on the processing

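The fits without TSP 1 and TSP 2, without slide 1 and of the main population pairs were chosen after seeing the data; the other alternatives were planned. Where no reason is given, the cause was not tested. The list calls of all contrasts together stayed within 1.5 times 57 under each alternative (49 to 64 with 1 array left out). None of the 95 named genes called in CSP against CMP changed direction under any alternative run. Differences that were not called did change sign, such as those of Vim (0.18), Tshr (-0.40) and Pax8 (-0.42) in TSP against CSP without TSP 1 and TSP 2 (with all arrays -1.64, 0.66 and 0.70). The scan day divides the arrays as the slides do and was not run separately. Spots well above background ranged from 38.8% to 72% per array, which limits dim genes most on slides 1 and 5.

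CSP against CMP gave 3041 genes, but 460 with normalization between arrays, 6110 with array weights, 2004 with the replicate block, 5785 with slide as a block and 0 within slide 4 (limma, 4371 unadjusted; fewer arrays), and 565 to 3352 with 1 array left out. The 16 named genes of this contrast kept 4 calls with normalization between arrays, 0 within slide 4 and 7 to 16 with 1 array left out. TSP against TMP gave 0, but 1 without background subtraction, 1 without a filter, 1 with an intensity trend, 754 with array weights, 236 with slide as a block, 238 within slide 5, and 0 to 615 with 1 array left out. It gave 3014 without TSP 1 and TSP 2 and 2869 without slide 1; without TSP 1 and TSP 2 and with a further change it gave 3241 (slide block), 3146 (processed signals), 3435 (no background subtraction), 2322 (median centring), 2474 (between arrays), 3402 (Cy5 alone), 2902 (value table) and 3007 (outlier spots kept). TSP against CSP gave 0, but 1 with the replicate block, 899 with slide as a block, 8315 within slide 1, 18 without TSP 1 and TSP 2 with slide as a block, and 0 to 3 with 1 array left out.

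TMP against CMP gave 0, and 0 to 0 with 1 array left out, but as pairs 6, and then 9 (no background subtraction), 2 (between arrays), 2 (Cy5 alone), 6 (outlier spots kept), 7, 29 and 332 (without pair 1, 2 and 3). The interaction gave 0, and 0 to 0 with 1 array left out, but 1 without TSP 1, TSP 2 and background subtraction. Calls shared by the side against main population contrasts were 0, but 1 without background subtraction, 1 without a filter, 1 with an intensity trend, 737 with array weights, 231 with slide as a block, 2567 without TSP 1 and TSP 2, 2262 without slide 1, 2425 without TSP 1 and TSP 2 with slide as a block, and 0 to 585 with 1 array left out. Median centring moved the median of all genes to 0.243 in TSP against CSP (loess -0.0355) and to 0.187 in the interaction (loess -0.0353).

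Among lists called with all arrays, means reversed in 2 contrasts; means of lists that were not called also changed sign. In TSP against CSP, within slide 3, without TSP 1 and TSP 2, without slide 1, and without TSP 1 and TSP 2 with slide as a block, they were -0.103, -0.169, -0.284 and -0.161 (follicular), 1.1, 0.396, 0.653 and 0.712 (fibroblast) and 0.21, 0.0369, 0.0673 and 0.0931 (mesenchymal transition). Epithelial genes gave -0.282 within slide 3, -0.367 without slide 1 and -0.261 in the last of these. Macrophage genes gave -0.0844 within slide 3 and -0.645 between arrays, and ribosomal genes 0.209 between arrays. In the interaction, the last 3 of these alternatives gave -0.188, -0.302 and -0.179 (follicular) and 0.391, 0.648 and 0.702 (fibroblast), the last 2 gave -0.366 and -0.26 (epithelial), and the last gave 0.0221 (mesenchymal transition). Normalization between arrays gave 0.102 (immediate early), 0.0382 (cytokine) and 0.237 (ribosomal).

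Of the other values of named genes, 3237 kept their side of the threshold in CSP against CMP, 442 lost the call and 22 gained it; in the other contrasts 91 (TSP against TMP), 29 (TSP against CSP) and 3 (TMP against CMP) gained it. Of the list values 31, 28, 34, 3 and 37 lost the call and 23, 8, 51, 24 and 25 gained it in the 5 contrasts.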

Other observations

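The tests of the 2 patterns below were chosen after the results were seen; the counts over other splits of the arrays were planned, except those without TSP 1 and TSP 2 and with the pairs as a block.

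Side population cells had lower follicular and epithelial and higher fibroblast and endothelial gene expression. Slide and scan day as the whole cause are argued against by the smallest mean shift of the 4 lists within slides 4 and 5, which was 1.81 in the direction of all arrays. Fewer follicular cells with all other cell types raised alike are argued against by macrophage genes, with an upper quartile of -0.225 where endothelial genes had a lower quartile of 2.52. Endothelial and fibroblast cells among the sorted cells, and side population cells that themselves express these genes, cannot be told apart: 90% of the endothelial and fibroblast genes (36 of 40) were higher by 1 or more (log2), which restates the pattern and follows from either. Of the 5 brightest fibroblast genes Col1a2 (mean log2 intensity 15.8, log2 difference 2.91) and Dcn (15.1, 4.26) were called, and Sparc (15.4, 0.80), Col3a1 (15.3, 3.57) and Col1a1 (14, 2.63) were not; of the 5 brightest endothelial genes Kdr (14.1, 2.42), Flt1, Egfl7 and Mmrn2 were called and Cldn5 (13.1, 0.81) was not. A gate against the surface proteins Pecam1 and Pdgfra would remove cells of either kind that carry them, so it would not tell the 2 apart.

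The cholesterol synthesis list was shifted down in the main population after surgery. Slide and scan day are argued against by the mean shift nearest to 0 among the 3 pairs on the same slide, which was -0.382 (farthest -0.767), and normalization by the list mean nearest to 0 over 6 other normalizations, -0.544 (farthest -0.693). Fewer follicular cells are argued against by the lower quartile of follicular genes, -0.115, against a median of -0.599 for cholesterol genes. A response of the main population cells to the surgery stays open, as a biological explanation that was not tested here.

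Other splits of the same arrays were counted with limma. For CSP against CMP 1 of the 84 splits, the real one, gave as many as 3041 genes, a share under 0.05, and the highest other gave 7. Every other split mixes the 2 populations within a group, which raises the spread and keeps its count low. CSP and CMP share only slide 4, so these splits cannot tell population from slide. Where the real count was 0, every split reached it by construction, so these counts say nothing about chance. This holds for TSP against TMP (84 of 84 splits; 2796 at an unadjusted p under 0.05), where the highest other, TSP 1, TSP 2 and TSP 6 with the TMP arrays, gave 3267, which points to a structure of the samples. It also holds for TSP against CSP (real 0, 100 of 100 drawn splits; 1857 unadjusted), where the highest other gave 1294 and set CSP 1 to CSP 4, TSP 3 and TSP 4 apart, which holds all of slide 3, where the blocked count was 899 and that within slide 3 was 0. And it holds for the interaction (real 0, 100 of 100 drawn splits, highest other 0; 219 unadjusted). For TSP against TMP without TSP 1 and TSP 2, 1 of 35 splits gave as many as 3014 genes and the highest other gave 1665, with arrays left out for their profile. TMP against CMP allows 10 splits, too few for a share under 0.05 (real 0 with 24 unadjusted, highest other 0; 10 of 10 as large), and so does the paired fit with 4 splits (real 6, highest other 0; 1 as large).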
